A study of Mus musculus with 2 samples.

How the data were processed

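Enhanced crosslinking and immunoprecipitation (eCLIP) maps the RNA fragments that copurify with a protein after crosslinking, and compares them with an input library made from the same kind of lysate without the pull-down. Per the labels' protocols, mouse neural progenitor cells from cortex were lysed and sonicated, RNA was trimmed with RNase I, and UPF1 with its bound RNA was pulled down with an antibody against UPF1. The cells carried a loxP-flanked Upf2 allele (genotype Upf2fl/fl) and the libraries are labelled MOCK, a word the labels do not explain. There was 1 immunoprecipitate and 1 input, with no replicate of either, so nothing in this data set measures the spread between cultures, and no p-value across genes or clusters was computed. The input has no table of its own here and enters only through the fold and p of each cluster.

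The deposited file lists stranded clusters, the stretches of RNA in which a caller found immunoprecipitate reads piled up. The authors gave each cluster a log2 fold of the immunoprecipitate over input and a −log10 p for that fold. The file has no header, so both units were taken from the values and from the customary layout of such files. The −log10 p values that the authors deposited run from 0 to a cap of 400, and all 32999 clusters with a fold at or below 0 are listed with 0, so depletion carries no test. The submitters' processing notes name UMI-tools, cutadapt, STAR and the mouse build mm10. The cluster caller, the formula of the fold and any filter on clusters are not given in the sources used here. The clusters do not overlap each other on a strand, and 6534 of them touch the one before. Because clusters were called on the immunoprecipitate, RNA that was not bound enough to give a cluster is missing from the list, and the median fold of all clusters lies above 0.

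Both deposited columns moved in steps, which allowed the read counts behind them to be reconstructed. If the commonest fold stands for 3 immunoprecipitate reads against 1 input read, the log2 scale between the libraries is -1.02, meaning that the immunoprecipitate held 2.03 times the reads of the input. With that scale, 99.8% of 400 sampled pairs of fold and p matched whole read counts. The p of those counts came from an exact binomial test (fewer than 5 reads on either side) or a chi-square test with continuity correction (otherwise). The other scales tried matched at most 16.0%. A match needed a p within 0.05 or 1% of the deposited −log10 p. In all, 90062 of 90350 clusters with a fold above 0 were reconstructed (99.7%), and 14102 of the 14330 enriched ones. Clusters at the cap of 400 and clusters at or below 0 were not. Input counts under 1 were not tried in the reconstruction, so a count of 1 may also stand for an input without reads. Intervals on folds are exact Clopper-Pearson 95% intervals from these counts, and intervals on shares are Wilson 95% intervals. Where a share is 0, the text gives instead the limit of 3 counts over the total, which differs from the Wilson bound. All cover counting error only, and those on folds rest on the reconstruction. Clusters of the same gene are not independent. For shares and medians by distance class, and for the near and far comparison of deep clusters, genes were therefore resampled 1000 times instead. Wilson intervals on other shares of clusters treat clusters as independent and are likely too narrow.

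Clusters were assigned to gene loci of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. That table gives the outer coordinates, type and symbol of each locus, without strand, exons or untranslated regions, and no genome sequence was used here. A cluster went to the locus covering most of its bases. The strand of a locus was taken as that of at least 80% of its clusters lying in no other locus (2 or more). Where loci overlapped, the cluster went to the locus on its strand, or to the only protein-coding locus among those left. This placed 114247 clusters in a sole locus and 6145 in overlapping loci. It left 1984 without a decision and 973 outside every locus. The distance to the 3′ end is the genomic distance, introns included, from the cluster's midpoint to the outer end of the locus on that strand. Because strands were taken from the clusters themselves, the share of clusters on the strand of their locus carries no information of its own.

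Enriched clusters were those with a log2 fold of at least 3 and a −log10 p of at least 3. For each fixed gene list, the median over genes of the highest fold in the gene, and the share of genes with an enriched cluster, were ranked among 10000 random lists of the same size, matched on the number of clusters per gene, since the file holds no expression level. A percentile of this kind describes these 2 libraries and is not a test between conditions. Where lists were matched on immunoprecipitate reads instead, the matching took away part of what was ranked, since those reads are part of the fold and, with an input count of 1, set it. These thresholds, the lists, the percentile and most alternatives were fixed before the data were examined. The design had also planned shares by coding sequence and untranslated region, position along and length of the 3′ untranslated region, GC content and exon junctions downstream of the stop codon. Each needs exon models or sequence and was not analysed here. Distance to the 3′ end of the locus took the place of the region classes, and all clusters of a locus took the place of those in exons or 3′ untranslated regions, also in the rule for named genes. This replacement, its limit of 5000 nt, the rules for overlapping loci and the reconstruction of read counts were chosen after seeing the data.

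The genes named were set by rule: the 10 with the highest fold of an enriched cluster, the 10 with the most nucleotides in enriched clusters, up to 4 enriched members of each list and up to 2 members without enrichment that had the most clusters, and 15 genes fixed in advance. The lists covered nonsense-mediated decay (NMD) factors, exon junction complex factors, known NMD targets, splicing regulators with poison exons, the p53 pathway, cell cycle, markers of progenitors, neurons, glia and non-neural cells, histones, ribosomal proteins, mitochondrial transcripts, microcephaly genes and cytoplasmic decay factors. Histone genes, linker histones included, and ribosomal protein genes were taken by symbol. The mitochondrial list was left empty because its symbols matched none in the reference, and no cluster is listed on that chromosome. Some genes that this rule takes are not reported here. Other genes are named in places and were then chosen after their values were seen.

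The scripts were tested on simulated reads placed on 33758 real cluster positions in 3000 loci. Of the simulated clusters with a fold above 0 and below the cap, 98.1% had their counts recovered. The simulated p came from the same formula that the recovery uses, so this recovery does not test the formula. Of clusters simulated at 16-fold, 96.2% were called enriched, and of those at 1-fold, 0.0044%. Simulated input counts mostly exceeded the median of 1 read reconstructed in the real list, so these call rates need not carry over to it. The list percentile was tested apart from these reads, on invented genes with randomly drawn cluster numbers and folds. Of 200 random lists of such genes, 4% fell outside the central 95% of the percentile of the median. A planted list of 20 genes with raised folds reached a percentile of 100. The percentile of the share was not tested in this way. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives covered the thresholds, merging, narrow clusters, overlapping loci, the matching of random lists and the input count.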

Results

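The data set describes where UPF1, the RNA helicase at the centre of nonsense-mediated decay (NMD), was bound on RNA in mouse cortical neural progenitor cells. NMD is the pathway that degrades transcripts whose translation ends prematurely. The comparison available here was the UPF1 immunoprecipitate against its input, with 1 library each. It listed 123349 clusters on 21 chromosomes, 62586 on the plus and 60763 on the minus strand, with a median width of 67 nt (quartiles 47 and 92). The file gives no library totals. From the reconstructed counts, an enriched cluster held a median of 63 immunoprecipitate reads (quartiles 38 and 117) and 1 input read, and a cluster with a fold above 0 that was not enriched held 5 and 1. The fold of a single cluster is therefore imprecise, and its counting interval is given with it.

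The first question was which RNAs were bound above input. UPF1 was enriched on 14330 of the 123349 clusters, 11.6% (Wilson 95% interval 11.4 to 11.8), with a median log2 fold of 4.29 among them. They fell in 3263 of the 9980 genes with a cluster (32.7%, interval 31.8 to 33.6). Nearly all were protein-coding: 3249 of 9679 protein-coding genes had an enriched cluster (33.6%, interval 32.6 to 34.5), against 14 of 235 long non-coding RNA genes (5.96%, interval 3.58 to 9.75). This contrast was not matched on the clusters or reads per gene, so a difference in either may contribute to it. Small structured RNAs lay below input. All 38 clusters on 26 snRNA, snoRNA, rRNA, tRNA, Y RNA, RNase P and RNase MRP loci had a fold below 0, with a median of -2.43. Among them were Rpph1, the RNA of RNase P (median -5.62 over 3 clusters), and Rmrp, the RNA of RNase MRP (median -5.33 over 2). None of these 38 was enriched, which allows a share of up to 7.89%. Over the whole list 577 clusters had a log2 fold of -3 or lower, for which the authors' deposited list gives no p above 0. Of these, 365 lay in a sole protein-coding locus and 104 in a protein-coding locus that overlaps another. Protein-coding loci held 118644 clusters on their strand. On the small RNAs, 17 of the 38 clusters were this low, a far larger part of their total.

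Among single clusters, the highest fold was found in Ntrk2, the TrkB receptor for the neurotrophin BDNF (chromosome 13, 58806472 to 59133970, GRCm38), with a log2 fold of 8.25 (interval 5.76 to 13.55) from 618 reads against 1. Zfand3 reached 8.24 and Plpp3, a lipid phosphate phosphatase, 8.23. Scd2, a stearoyl-CoA desaturase of fatty acid synthesis (chromosome 19, 44293676 to 44306864), reached 8.06 (interval 6.20 to 11.10) from 1082 reads against 2, and all 59 of its clusters were enriched. Zcchc24 reached 8.03, Ivd, an enzyme of leucine breakdown, 7.99, Nedd4, a ubiquitin ligase, 7.94, Prdx6, a peroxiredoxin, 7.92, and Fbxw11, an F-box protein, 7.85. Ednrb, the endothelin B receptor, reached 7.98, but all 27 of its clusters also lay inside a second annotated locus. The intervals of these 10 overlap, so their order is not resolved.

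Genes were also ranked by their nucleotides in enriched clusters, which need not be adjacent, and Ntrk2 and Scd2 are in both rankings. The most nucleotides in enriched clusters were found in Ntrk2 (2517 nt), followed by Sdc3, a cell-surface heparan sulfate proteoglycan (1947 nt), Ttyh3 (1885 nt), Adcyap1r1, the PACAP receptor (1883 nt), Sbk1 (1853 nt), Scd2 (1818 nt), Nfib, a transcription factor of glial and neuronal development (1747 nt), Bpnt2 (1695 nt), Ago1, an Argonaute protein (1624 nt), and Nfix, a relative of Nfib (1584 nt). The number of enriched clusters per enriched gene had a median of 3 and a maximum of 59, 955 genes had only 1, and the 100 genes with the most held 14.0% of all enriched clusters assigned to a gene.

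The second question was where along the gene UPF1 lay. Enriched clusters gathered at the 3′ ends of protein-coding genes. Of 13842, 12704 lay within 5000 nt of the annotated 3′ end (91.8%, interval 91.3 to 92.2). Of 104802 clusters that were not enriched, 24149 did (23.0%, interval 22.8 to 23.3). These intervals, and those for the first and last 1000 nt of long loci below, are Wilson intervals that treat clusters as independent. Of clusters in the last 1000 nt, 35.9% were enriched (interval over resampled genes 34.6 to 37.3). The share was 40.3% between 1000 and 2000 nt from the end (38.6 to 41.9), 28.4% between 2000 and 5000 nt (26.8 to 30.1), and 8.24% between 5000 and 10000 nt (6.82 to 9.77). Beyond 20000 nt it was 0.483%, 308 of 63714 clusters. The median log2 fold went from 2.83 at 1000 to 2000 nt (2.78 to 2.88) to 0.56 at 10000 to 20000 nt, where 0.56 is the value of 3 reads against 1. Enrichment was rare at 5′ ends. In loci of at least 10000 nt, 47 of 2403 clusters in the first 1000 nt were enriched (1.96%, interval 1.47 to 2.59), against 4271 of 11513 in the last 1000 nt (37.1%, interval 36.2 to 38.0). Distances include introns, and clusters in exons could not be told from clusters in introns. The gradient therefore describes position along the locus and need not hold along the spliced mRNA. Whether a cluster lay in the 3′ untranslated region itself was not analysed here.

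**Figure D1:**
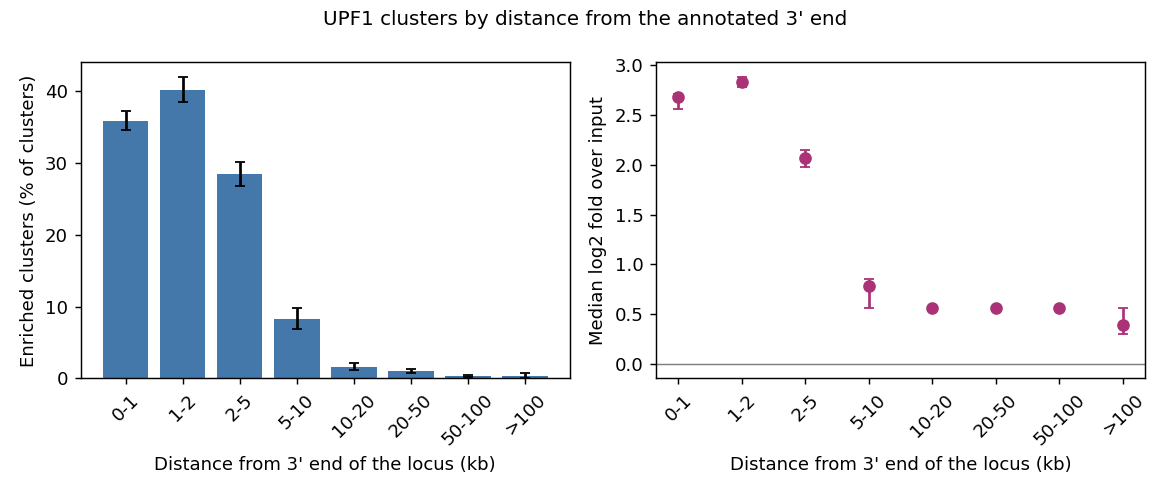
Share of clusters that were enriched (left, percent) and median log2 fold over input (right) against the genomic distance from the annotated 3′ end of protein-coding loci (kb). Bars and points are values of the single library pair, and error bars are 95% intervals from 1000 resamplings of genes; enrichment was most frequent in the first 3 distance classes, at 35.9%, 40.3% and 28.4%.

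Transcripts of the decay machinery were among those bound. Of the 15 NMD factors with a cluster, 6 had an enriched one (40.0%, interval 19.8 to 64.3). Pnrc2, a decapping cofactor, had 7 of 8 clusters enriched, with a highest log2 fold of 6.39 (interval 3.89 to 11.70). Upf1 itself (chromosome 8, 70331493 to 70353423) had 5 of 6 clusters enriched and reached 5.37 (interval 2.85 to 10.69), 183 nt from its 3′ end. Smg5 reached 4.76. Upf2 had 1 of 10 clusters enriched, with a fold of 3.78 from 28 reads against 1, and it was not called with a −log10 p of at least 5. Smg1, the kinase of UPF1, had 31 clusters and none enriched, with a highest fold of 2.93, and was called with a fold threshold of 2. None of the 13 clusters of Upf3b passed, with a highest fold of 1.44, and none of the 25 of Smg6 did, with 2.30 among the clusters assigned to it. The 3′ end of Smg6 overlaps the locus Hic1, and 7 clusters there, all on the plus strand like the best cluster of Smg6, were assigned to neither gene. Of these 7, 6 were enriched, with a highest fold of 5.32, so Smg6 cannot be counted as unbound. The list, with Smg6 counted as not enriched, lay within the range of other genes: its median highest fold lay at the 34.3rd percentile of matched random lists.

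Of the 7 exon junction complex genes with a cluster, which encode proteins left on spliced mRNA, 4 had an enriched cluster. These were Acin1 (5.93), Rbm8a (5.80, with all 5 clusters enriched), Casc3 (4.98) and Rnps1 (4.47). Sap18 and Pnn had none, with highest folds of 2.56 and 1.88. The median of this short list lay at the 99.0th percentile of random lists matched on cluster number, but at the 62.2nd when matched on immunoprecipitate reads. Acin1 and Rnps1 were not called when clusters with an input count of 1 were left uncalled.

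Transcripts known as NMD substrates did not stand apart from random lists. Of 29 with a cluster, 7 had an enriched one (24.1%, interval 12.2 to 42.1), at the 36.5th percentile for the median fold. Gabarapl1, an autophagy gene, reached 5.36 (interval 3.48 to 8.42), Atf4, the transcription factor of the integrated stress response, 5.20 (interval 2.68 to 10.53), Ptbp2, a neuronal splicing repressor, 4.70, and Gadd45g, a growth-arrest gene, 4.59. Gas5, a snoRNA host RNA, had 9 clusters with a highest fold of 1.78, and Slc7a11, the cystine transporter, 15 clusters with a highest fold of 2.85, called with a fold threshold of 2. Among splicing regulators that carry poison exons, 7 of 23 were enriched (30.4%, interval 15.6 to 50.9) where random lists averaged 51.5%. Srsf2 reached 5.85, Hnrnpk 4.62 and Srsf11 4.06, while the 33 clusters of Hnrnpm reached 1.98 and the 27 of Tra2a reached 3.44 without passing the p threshold. This list lay at the 1.94th percentile for its share and the 10.4th for its median fold. The share lay inside the central 95% with the fold threshold at 2 (26.6th percentile), and Srsf2 was not called without clusters whose input count was 1.

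In the p53 pathway, 11 of 22 genes had an enriched cluster (interval of the share 30.7 to 69.3%), at the 72.5th percentile for the median. Sesn1 and Sesn2, stress-induced regulators of mTORC1, reached 6.61 (interval 4.11 to 11.92) and 5.30. Zmat3, an RNA-binding p53 target, reached 5.50 and had 11 of 20 clusters enriched. Trp53inp1 reached 5.20. Trp53, which encodes p53, had 6 clusters and none enriched, with a highest fold of 1.78. Cdkn1a, the cell cycle inhibitor p21, reached 3.15 without passing the p threshold. Mdm2, Mdm4 and Trp53bp1 had none enriched either, with highest folds of 2.15, 2.78 and 2.44. Of 18 cell cycle genes, 4 had an enriched cluster (22.2%, interval 9.0 to 45.2, median at the 30.1st percentile): Rb1 at 5.26 and the D-type cyclins Ccnd1, Ccnd3 and Ccnd2 at 4.19, 3.98 and 3.88. The proliferation marker Mki67 had 12 clusters and Cenpf 11, with highest folds of 2.15 and 1.30.

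Markers of glia, progenitors and neurons were each ranked against random lists, and the lists were not tested against each other. Of the 13 glial markers with a cluster, all 13 had an enriched one (interval 77.2 to 100%), where matched random lists averaged 49.1%, and the median highest fold of 5.32 lay at the 99.95th percentile. Gja1, the astrocyte connexin 43, had 21 of 21 clusters enriched and reached 6.87 (interval 5.01 to 9.92). Gfap, the astrocyte intermediate filament, had 9 of 9 and reached 6.0 (interval 4.14 to 9.06). The myelin gene Cnp reached 5.87. Against random lists matched on immunoprecipitate reads, the median lay at the 74.5th percentile and the share at the 86.3rd. Of 21 progenitor markers, 13 were enriched (61.9%, interval 40.9 to 79.2, median at the 75.6th percentile), with Slc1a3, a glutamate transporter of radial glia and astrocytes, at 6.81 (interval 5.26 to 9.09). The RNA-binding proteins Msi2 and Msi1 reached 6.44 and 6.28, and Sox9 reached 5.92. Sox2 had 2 of 11 clusters enriched and reached 3.62, all inside the overlapping locus Sox2ot. Nes, the progenitor intermediate filament, had 2 of 9 and reached 3.37. Vim had 9 clusters and Notch1 40, none enriched, with highest folds of 1.65 and 3.50, and Tnc reached 2.15. Matched on immunoprecipitate reads, which are part of the fold being ranked, the progenitor median lay at the 0.91st percentile and the share at the 10.9th. Of 14 neuronal markers, 5 were enriched (35.7%, interval 16.3 to 61.2, median at the 24.8th percentile): among them Ncam1 at 6.17, Dcx at 5.53, Map2 at 5.47 and Mapt at 5.22, with Elavl4 and Syn1 at 2.68 and 1.78 and not enriched. Of 23 markers of microglia, vessels, fibroblasts and blood, 22 had no cluster, and the only cluster of Pdgfrb had a fold of 1.30.

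**Figure D2:**
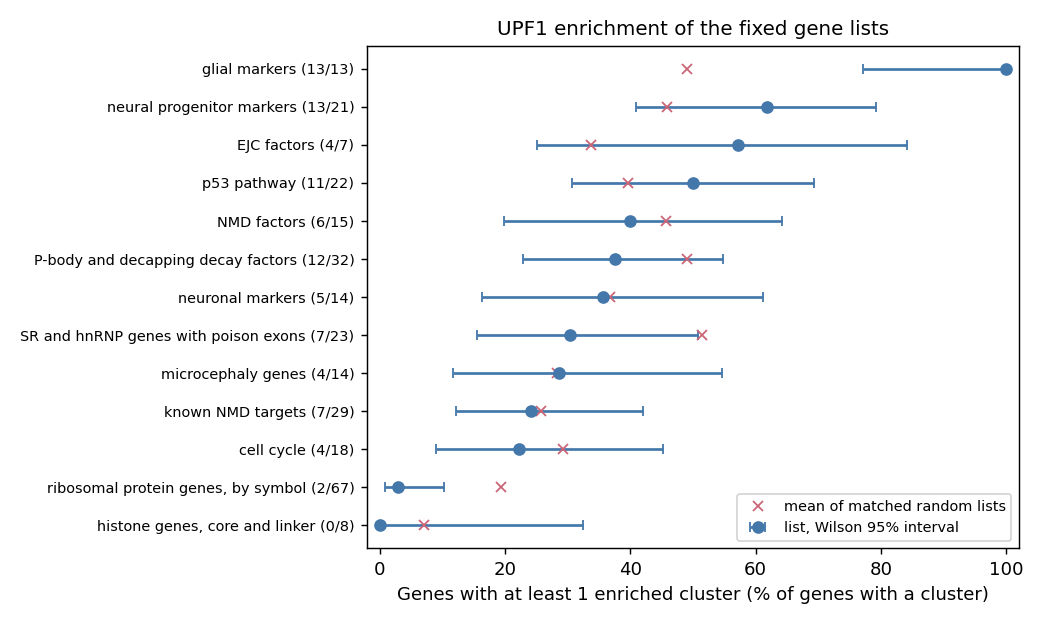
Percent of the genes with a cluster that had at least 1 enriched cluster, for each fixed gene list that had at least 5 such genes (circles, with Wilson 95% intervals; counts in brackets), and the mean of random lists matched on cluster number (crosses). Glial markers stood at 100% against 49.1% for random lists, and ribosomal protein genes at 2.99% against 19.5%.

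Few genes taken as ribosomal protein genes by their symbol were enriched. Of 67 with a cluster, 2 had an enriched one (2.99%, interval 0.822 to 10.2), and 2 of 66 did without Rps19bp1, which does not encode a ribosomal protein. Their median highest fold was 0.98, below all 10000 random lists. Matched on immunoprecipitate reads, the share lay at the 5.75th percentile (5.755), inside the central 95%, and the median at the 0.875th. The 2 were Rpl7l1, a paralog of a ribosomal protein gene, at 5.46 (interval 4.22 to 7.09), and Rpl22 at 5.19. Rps3 and Rpl13a had 11 and 10 clusters, with highest folds of 2.88 and 1.98. Histone genes, core and linker, were also taken by symbol, and UPF1 takes part in the decay of replication-dependent histone mRNAs. Clusters lay in 8 of 67 members, 3 of them the linker genes H1f1, H1f3 and H1f4, and none was enriched, which allows a share of up to 37.5%. H2bc21 reached 3.15 and H2bc6 1.98, and the list median lay at the 8th percentile, or the 12.5th without the linker genes. Other matchings and length-weighted folds put it below the central 95%, down to the 0.04th percentile when matched on immunoprecipitate reads, which are part of the fold. Near-identical histone copies share reads, so single histone values are uncertain.

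Microcephaly genes and cytoplasmic decay factors lay inside the central 95% of random lists. Of 14 microcephaly genes, 4 were enriched (28.6%, interval 11.7 to 54.6, median at the 6.86th percentile). They were Wdfy3 at 5.47, Knl1 at 3.98, Cdk5rap2 at 3.93 and Cit at 3.68, while Mcph1 and Ankle2 reached 1.56 and 3.30 without being enriched. Wdfy3 was not called when only clusters inside 1 locus were kept, where its highest fold was 2.68. Of 32 decay factors, 12 were enriched (37.5%, interval 22.9 to 54.7, median at the 6.62nd percentile). Ddx6, a helicase of P-bodies, reached 7.25 (interval 4.76 to 12.56) with 14 of 15 clusters enriched. Its partners Lsm14a and Lsm14b reached 6.04 and 5.38, and Tnrc6b, a microRNA effector, 5.39. Pan3 and Cnot4, members of deadenylase complexes, had 53 and 49 clusters, none enriched, with highest folds of 2.88 and 2.44.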

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

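The test of the highest folds was written after some of its result had been seen, the tests of the glial share after their results had been seen, and the random lists matched on immunoprecipitate reads or on clusters near the 3′ end were chosen after seeing the data. Signal also lay in clusters that no comparison of genes used. Outside every annotated locus, 132 clusters were enriched, 13.6% of the 973 there (Wilson interval 11.6 to 15.9), against 11.5% of assigned clusters. The highest, on chromosome 5 from 34175665 to 34175759, had a log2 fold of 7.19. A further 315 enriched clusters lay in overlapping loci with no single owner. Of these, 26 lay on chromosome 18 between 37808514 and 37841636, where 23 to 25 loci overlap, among them those of the gamma protocadherins, and their median log2 fold was 5.64.

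The highest folds were a first pattern. Among the 100 highest reconstructed enriched folds, 72% had an input count of 1 (Wilson interval 62.5 to 79.9), against 50.7% of all enriched clusters. A ranking by fold favours low input counts by construction. This larger share therefore cannot decide whether a low input sets the top of the ranking. The same 100 clusters held at least 258 immunoprecipitate reads each. Their lowest fold, 6.99, already requires this at an input count of 1 or more, so it is no separate evidence of depth. Ranking the reconstructed enriched clusters by −log10 p instead, which leaves out the 228 at the cap, gave another 100, of which 34 were shared and 6% had an input count of 1. Whether an input of 1 stands for no reads stays open, and no biological explanation was tested.

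The gathering of enriched clusters at 3′ ends was another pattern. Distant clusters hold few reads and could fail the thresholds for that reason. Among clusters at the p cap or with at least 24 reconstructed immunoprecipitate reads, 84.5% of 15042 within 5000 nt of the 3′ end were enriched, against 13.6% of 2267 beyond 20000 nt. The difference of 70.87 percentage points (interval over resampled genes 66.02 to 74.99) leaves out clusters with no reconstructed count, such as those at or below 0. Counting all 2185 of these within 5000 nt as deep and not enriched, and none far away, still left 60.2 points (55.0 to 64.3), a bound added after seeing the data, which argues against low depth as the whole cause. The enriched clusters near 3′ ends do not come from a few loci either. Of 3249 protein-coding loci with an enriched cluster, 3030 had one within 5000 nt (93.26%). This share does not measure the gathering itself, because no background share of loci was set beside it. Loci shorter than 5000 nt also meet it by their length alone. That UPF1 occupies 3′ untranslated regions is a candidate explanation that these coordinates cannot separate from the end of the coding sequence. Nor can they separate distance from the 3′ end from a difference between exons and introns, since distances include introns. No biological explanation was tested.

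Enrichment of all 13 glial markers with a cluster was weighed last. When random lists were matched on the highest immunoprecipitate read count per gene, the list's median fold lay at the 74.53rd percentile and its share at the 86.34th, so the number of reads on these genes may account for both. Matched on clusters within 5000 nt of the 3′ end, the median lay at the 96.72nd percentile, inside the central 95%, but the share at the 99.99th, which argues against such clusters as the source of the share. Read number and binding stay open, because immunoprecipitate reads rise with both and are part of the fold. The culture's makeup, which an input table or an expression table would show, was not analysed here, and no biological explanation was tested.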

How the results depend on the processing

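Most enriched clusters lay near the 3′ end under each alternative run, and the ribosomal median stayed at or below the 0.875th percentile, while counts and several list percentiles moved. The enriched count of 14330 became 8916 with a log2 fold of at least 4, 8674 after merging clusters within 50 nt and 7176 without calling clusters whose input count was 1, which also left 2080 of 3263 genes. The share within 5000 nt of the 3′ end (91.8%) was 89.9% and 89.2% with folds of at least 2 and 1, 93.5% with 4, 92.4% (92.35) with −log10 p of at least 5, 91.0% (90.97) after merging, 89.0% (88.99) counting each gene and region once, and 91.1% (91.08) without input counts of 1. With 2000 nt or 10000 nt as the limit it was 65.7% and 96.6%. Weighting clusters by width raised the median log2 fold to 2.98 (2.976), 3.19 (3.185), 2.56 (2.561) and 0.98 (0.9758) in the distance classes up to 10000 nt and left it in its interval beyond. Poison-exon splicing regulators, at the 1.94th percentile for their share, moved to 26.6 and 25.4 with folds of at least 2 and 1, 6.77 with the stricter p, 5.41 after merging and 8.32 without input counts of 1. Their median went from 10.4 to 0.01 when matched on clusters near the 3′ end and to 0.1 when matched on immunoprecipitate reads. The exon junction list's median (99.0) fell to 72.4 with length-weighted mean folds, 95.8 when matched near the 3′ end and 62.2 when matched on reads, and its share reached 97.7 with a fold of at least 1. The glial median (99.95) fell to 96.7 matched near the 3′ end, where the share stayed at 99.99, and to 74.5 matched on reads, where the share fell from 100 to 86.3. The progenitor list's median reversed from 75.6 to 0.91 when matched on reads, and its share reached 97.8 (97.85) after merging and 98.3 without input counts of 1. The p53 list reached 98.7 (median, length-weighted) and 98.6 (share, without input counts of 1), and decay factors 2.22 (2.225) for the share with the stricter p. The histone median (8) was 1.47 matched on total cluster length, 1.56 with length-weighted folds, 2.27 matched near the 3′ end and 0.04 matched on reads, and the ribosomal share rose to 5.75 (5.755), inside the central 95%, matched on reads. Matching on reads takes away part of the fold ranked; the cause was not otherwise tested for any of these. Of 96 named genes, 8 were not called with a fold of at least 4, among them Sox2 and Nes, 3 with the stricter p (Upf2, Cit and Knl1) and 7 without input counts of 1 (those, Acin1, Rnps1, Srsf2 and Tnrc6b). Smg1 and Slc7a11 were gained with a fold of at least 2, and Pnn and Vim also with 1. With 1-locus clusters only, Wdfy3 was not called, and Ednrb and Sox2 had no cluster left. Settings on the input count, 1-locus clusters, the distance limit, these 2 matchings and leaving out linker histones or Rps19bp1 were added after seeing the data. Orders of region classes, a choice of transcripts and a minimum 3′ untranslated length were not run, since no exon models were used, nor were the alternatives for the planned results not analysed. No paired analysis was possible because there was 1 library per group. Depth limits single folds, since with 1 input read a cluster needed 24 immunoprecipitate reads to pass.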

Other observations

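Further single genes were chosen after their values were seen, so they describe no group and were not set against random lists. Abat, an enzyme of GABA breakdown, and Glul, glutamine synthetase, reached log2 folds of 7.46 (interval 4.97 to 12.76) and 5.98, and the transporters Slc1a2 and Slc6a11 reached 6.83 and 5.87. Of genes of lipid and sterol synthesis, Fads1 reached 7.14, Elovl5 6.24, Scd1 5.73, Hmgcs1 5.44 and Fasn 5.22, while Sqle (1.78) and Elovl6 (3.37) had no enriched cluster. Nfia had 13 of 197 clusters enriched with a median fold of 0.56, and Nfix 22 of 38 with a median of 3.31. Among the Argonaute genes the values were uneven: Ago1 had 20 of 23 clusters enriched and reached 6.0, Ago2 and Ago3 had 1 each and reached 3.37 and 3.44, and Ago4 had none.

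Long non-coding RNAs were mostly not enriched. Malat1, an abundant nuclear RNA, had 74 clusters and none enriched, and its highest log2 fold, 1.72, stood at the p cap of 400. Miat and Sox2ot reached 2.83 and 2.78. Of the 14 long non-coding RNA genes with an enriched cluster, D030047H15Rik had the highest fold, 6.72, with 4 of 4 clusters enriched. AU020206 had 6 of 14 with 5.06, Tug1 5 of 10 with 4.93, and A230056P14Rik 3 of 4 with 4.33.

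Some enriched clusters lay deep inside genes, 308 of them beyond 20000 nt from the 3′ end in 124 loci. Ntrk2 held 48 and had none within 5000 nt of its annotated end. Of these, 45 lay between 58932888 and 58936596 on chromosome 13, with a median log2 fold of 6.18. Prdm16 held 15. Ntrk2 is known to make a truncated receptor from an internal 3′ end, and where these clusters lie relative to it was not analysed here.

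The hypothesis that transcripts run past annotated 3′ ends was tested on the enriched clusters outside loci, with its prediction written before the result was seen. Of those lying within 10000 nt of a locus on the same strand on only 1 side, 97 were downstream and 3 upstream, a downstream share of 97% (Wilson interval 91.5 to 99.0). This is consistent with 3′ ends longer than this annotation gives. Of the outside clusters that were not enriched, 361 were downstream and 68 upstream, 84.1% (interval 80.4 to 87.3).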
